A study of Mus musculus with 12 samples.

How the data were processed

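Total RNA of mouse embryonic stem cells was prepared on silica columns with DNase treatment, and 100 ng per sample was labelled with Cy3 and hybridised to Agilent mouse arrays, per the labels' protocols. The 12 samples fell into 4 groups of 3 by the treatment and replicate number in their titles, and the series' design text describes them as biological replicates; p-values measure the spread between these samples. Doses were 250 nM 4OHT for 6 h and 1 µM MG132, given 30 min before and then for 6 h, in medium with 250 nM PD173074, per the labels. No vehicle control was named. The titles put the untreated cells at 0 h, and no untreated group at 6 h was among the arrays, so time and compound change together in each comparison with untreated cells.

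The authors deposited 1 scanner file per array with intensity values from Agilent Feature Extraction 11.0.1.1, per the file headers. The processed intensity is the spot's brightness after background subtraction and detrending within the array, per the file headers, with no scaling between arrays. The series-wide values the authors deposited held the same processed intensity, with a largest difference of 0 and column medians from 18.0 to 27.6, so their scale is that of the scanner and nothing was centred. Each array held 62976 spots, of which 3671 were control spots and were left out, as were spots with an outlier mark. No spot was saturated and no pair of arrays was identical.

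Spots of one probe were averaged (300 probes lay on 10 spots each), which left 56605 probes. The scanner files used here held accessions but no gene names, so accessions were matched without their versions to RefSeq gene names of the GRCm38.p6 assembly: 32994 probes (58.3%) received a symbol and 23611 kept their accession. Coordinates were not used, since the array design names an older build. The log2 of the processed intensity minus the 75th percentile of each array (309 to 485 intensity units) was used. Probes well above background on all arrays of at least 1 group were kept (34327), and each gene was represented by its probe with the highest mean over all arrays, giving 26836 genes, 15981 of them with a symbol. Probes of one gene disagreed in direction, both called, in 37, 124, 47, 144 and 0 genes in the order of the comparisons in the report; none was a named gene. A group in which no array was well above background has only a bound, so the fold is given as at least the ratio of the bright group's mean to the mean, per array, of the higher of the lowest signal well above background and the probe's own signal.

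limma 3.58.1 (R 4.3.3) was fitted with 1 coefficient per group over all 12 arrays (8 residual degrees of freedom, 2.08 prior degrees of freedom), with Benjamini-Hochberg adjustment and a threshold of 0.05. A total of 5 contrasts was tested, including the difference between the 4OHT responses with and without MG132. An exact test on 3 against 3 arrays cannot give a p below 0.1, so no exact test was run on single genes. Files were read with the data.table package, version 1.17.8, and jsonlite 2.0.0, and plots drawn with Python 3.11.15, matplotlib 3.10.9 and numpy 2.4.6.

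The design, the rule for named genes, the alternatives and 22 gene lists (442 genes) were fixed before the data were examined. The lists were ERK immediate-early genes, ERK feedback and ETS targets, naive pluripotency, general pluripotency, primitive endoderm, formative and primed epiblast, mesendoderm, trophoblast, neural progenitor, fibroblast and feeder cell, 2-cell-like state, proteasome subunits, cytosolic heat shock response, NRF2 and metal response, ATF4 integrated stress response, endoplasmic reticulum chaperones, p53 targets, Wnt beta-catenin targets, cholesterol synthesis, BMP and SMAD targets, LIF and STAT3 targets, and mitotic cell cycle. Some genes belong to more than one list. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over 110 list tests; 108 genes with a missing value, 2 of them list members, did not enter camera. Named genes were, per comparison, the 8 largest called rises and falls with groups apart, the 2 largest bounds in each direction, up to 3 called members of each list with the largest change, and 10 fixed genes; for MG132 with 4OHT against 4OHT alone, the 5 largest rises and falls. The bounds could not be formed for the difference of responses. Other genes are said to have been chosen after their values were seen. Results of a few named genes are not reported here.

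Alternatives were normexp background correction (offset 50), quantile normalization, median centring, no filter, a filter on all 12 arrays, the mean over probes, array weights, an intensity trend with robust variance, only the arrays compared, slide as a fixed or random block, arrays within a slide, a replicate block, the series-wide values, a 2-fold minimum and leaving out each array. Normexp was planned on mean signals but was run on median signals, because the files used here give medians. Same-numbered arrays were checked for shared deviations from their group means. Correlations across genes for replicates 1, 2 and 3 were 0.16, 0.14 and 0.41 between MG132+4OHT and MG132. There MG132+4OHT replicate 2 correlated more closely with an MG132 array of another number, so a pairing of all arrays by number was not shown. For the other comparisons at least 1 pair lay below 0.1. On simulated data with 50 changed genes per size among 26728 genes, the share of 2-fold changes recovered was 62% for 4OHT against untreated, 64% for MG132 against untreated, 68% for 4OHT under MG132, 60% for MG132 under 4OHT and 48% for the difference of responses, and of 4-fold changes 90%, 90%, 84%, 88% and 78%. The share of false calls was 5.56%, 6.08%, 6.58%, 6.29% and 6.03%. Far fewer genes were changed there than were called in the data, and the noise was independent with 1 spread per gene for all groups. These shares therefore describe the simulated data only.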

Results

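Gene expression was measured on 12 one-colour microarrays in mouse embryonic stem cells, which are pluripotent cells from the early embryo. The cells were grown with leukaemia inhibitory factor (LIF) and with PD173074, an inhibitor of fibroblast growth factor receptors, which signal to the kinase ERK. How far this signalling was blocked was not measured on the arrays. The arrays covered 4 conditions with 3 arrays each: untreated cells, cells given 4OHT for 6 h, cells given the proteasome inhibitor MG132, and cells given MG132 before and together with 4OHT. The untreated arrays were titled as 0 h, and no array was titled as untreated at 6 h, so the hours of treatment differ together with the compound wherever untreated cells were the control. The series title names proteasome and ERK dependent transcription, and 4OHT is a ligand widely used to switch on proteins fused to a modified oestrogen receptor. The labels used here do not name the fusion protein. Between 49.4% and 63.2% of the 56605 probes lay well above background on each array, and the number of arrays limits the precision. Across genes, arrays of one group correlated at 0.993 to 0.996 in untreated cells, 0.976 to 0.982 with 4OHT, 0.987 to 0.993 with MG132, and 0.993 to 0.996 with both. Slide 1 held 8 arrays, the untreated and 4OHT arrays with MG132 replicates 1 and 2, and slide 2 held 4 arrays, MG132 replicate 3 and the arrays with both compounds. The replicate 3 arrays of all groups differed together from their partners in 2721 genes. Among these, imprinted Mest was higher by 6.42 ± 0.31 on the log2 scale, 9 of 20 primitive endoderm markers were higher, and 6 of 11 markers of the 2-cell-like state were lower. Lower members were also found for ATF4 targets (7 of 22), NRF2 and metal response genes (9 of 20), formative genes (7 of 17) and neural genes (4 of 12, with 1 higher), and higher ones for cholesterol genes (9 of 22, with 2 lower). Mitotic genes (median -0.13, adjusted p = 0.00074, and 0.14 with an estimated correlation) and proteasome genes (median 0.088, adjusted p = 0.029, and 0.60) also passed the camera test between these arrays. The only MG132 array on slide 2 was replicate 3. Values with slide as a block or within a slide therefore carry this deviation wherever MG132 arrays enter. A fit with slide and replicate blocks together, chosen after the data were seen, holds both as terms. All changes are log2 fold changes with their standard error (SE), n = 3 arrays per group, unless a fold is given, and adjusted p values are those of limma. Each SE rests on 1 spread per gene pooled over all 12 arrays, not on the arrays compared alone. Deviations from the group means had an SD of 0.39 to 0.45 on the 4OHT arrays and 0.19 to 0.29 on the others. The pooled spread is on average too small for pairwise comparisons with the 4OHT group and too large for those without it. With only the arrays compared, calls went from 7667 to 5072 for 4OHT against untreated and from 7109 to 8227 for 4OHT under MG132.

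The first comparison, of 6 h of 4OHT with untreated cells at 0 h, asked what 4OHT changed while the proteasome was active. Egr1, an immediate-early transcription factor induced by ERK signalling, rose 8.52-fold (3.09 ± 0.21, adjusted p = 4.6e-06). Spry4, which encodes a feedback inhibitor of receptor tyrosine kinase signalling, rose by 3.33 ± 0.21 (adjusted p = 3.0e-06), and Dusp6, which encodes an ERK phosphatase, by 2.33 ± 0.18 (adjusted p = 1.1e-05). Nanog, a core factor of naive pluripotency, fell by 2.43 on the log2 scale (SE 0.13, adjusted p = 1.4e-06), and the factors Klf4 and Esrrb changed by -2.39 ± 0.28 and -1.01 ± 0.13. The chemokine gene Ccl20 was at least 595-fold higher and the trophoblast regulator Cdx2 at least 117-fold higher, since neither was well above background in untreated cells. In each of these genes all 3 4OHT arrays lay on one side of all 3 untreated arrays.

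**Figure D1:**
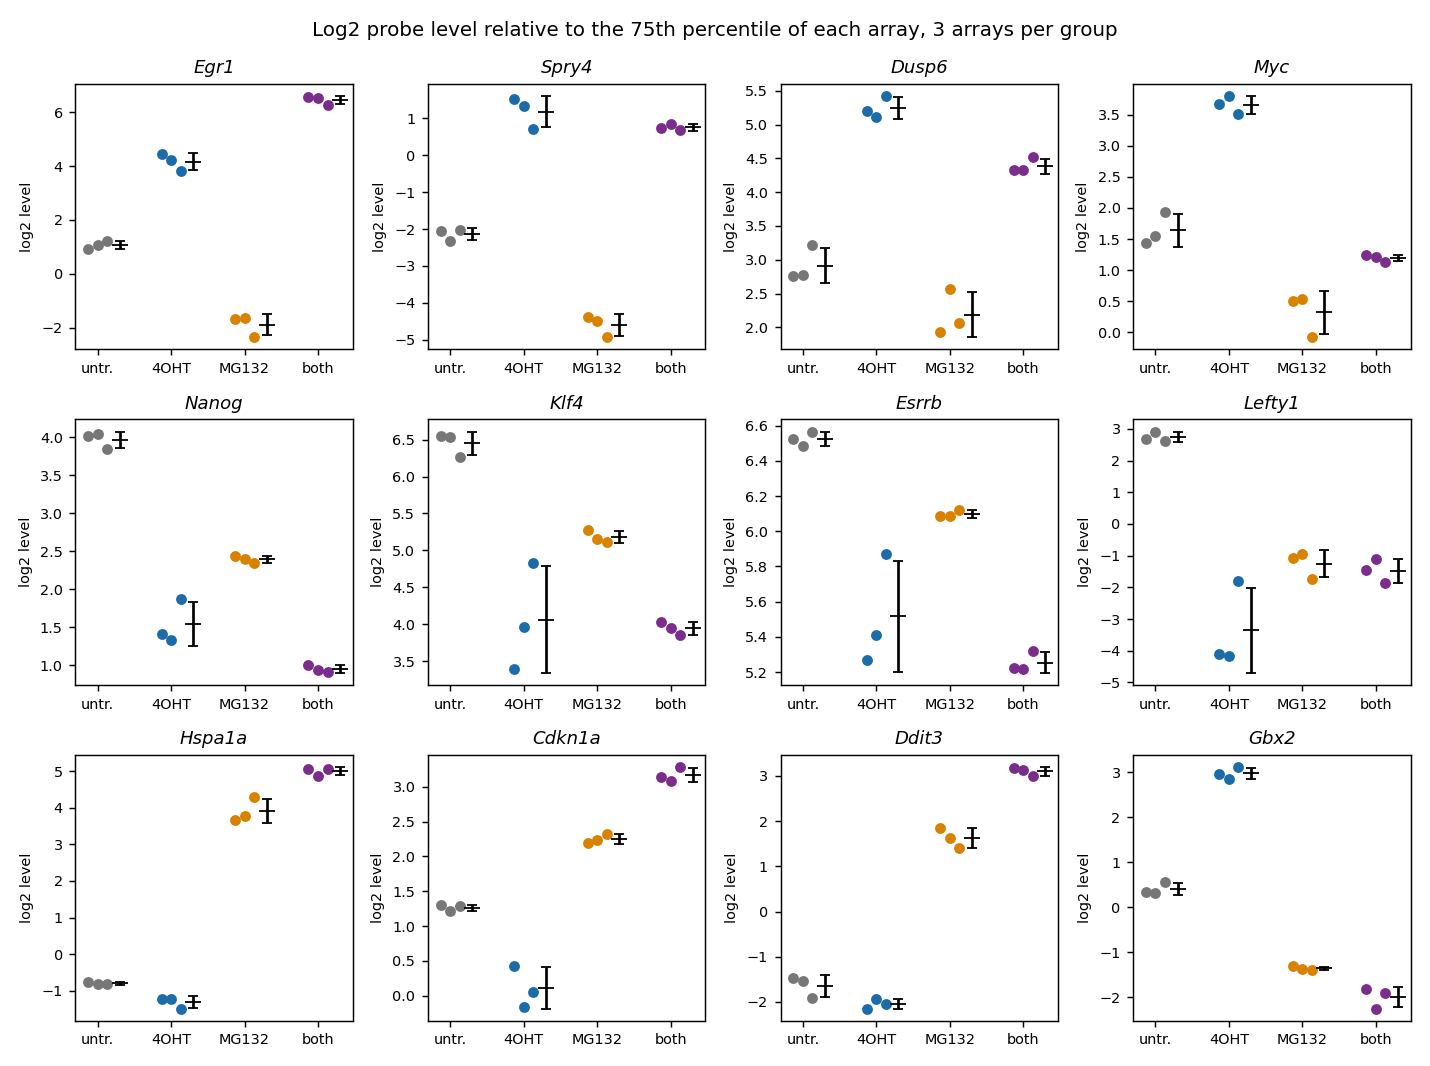
Log2 probe level relative to the 75th percentile of each array for 12 genes; each point is 1 array, filled where the probe was well above background, and the black marks give the mean and SD of the 3 arrays of a group (untr., untreated; both, MG132 with 4OHT). Egr1 lay lowest with MG132 alone and highest with both compounds, a 4OHT response of 3.09 without and 8.35 with MG132 on the log2 scale.

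Of 22 measured ERK immediate-early genes, 14 rose with 4OHT and 2 fell, with a median of 0.87 (camera, adjusted p = 1.6e-06; adjusted p = 0.16 with an estimated correlation). Counts of 15 that rose and 2 that fell were obtained adjusted over the list alone. The largest rises were Egr3 (at least 67.8-fold), the AP-1 subunit Fosl1 (5.02 ± 0.34) and Ier5 (3.58 ± 0.13), while Egr4 (-0.89) and Srf (-0.42) were the members that fell. Of 23 ERK feedback genes and targets of ETS factors, 16 rose and only the cyclin gene Ccnd1 (-1.18) fell, with a median of 1.40 (adjusted p = 1.6e-08; adjusted p = 0.16 with an estimated correlation). Adjusted over the list alone the counts were 17 and 2. Among them were Phlda1 (5.36 ± 0.26) and the phosphatase genes Dusp5 (3.89 ± 0.24) and Dusp2 (3.78 ± 0.24). Of 20 naive pluripotency genes, 12 fell and 3 rose, with a median of -1.05 (adjusted p = 0.0036; adjusted p = 0.31 with an estimated correlation). Counts of 13 that fell and 3 that rose were obtained adjusted over the list alone. The members that rose were Klf5 (0.79), Nr0b1 (0.76) and Gbx2 (2.57 ± 0.13). Of 17 formative and primed epiblast genes, 10 rose, with a median of 0.86 (adjusted p = 0.00033; adjusted p = 0.16 with an estimated correlation), among them the POU factor Pou3f1 (3.94 ± 0.29) and the ETS factor Etv4 (2.63 ± 0.14); Sall2 fell (-1.76). Counts of 11 that rose and 1 that fell were obtained adjusted over the list alone. Single members of these lists given without an SE were chosen after their values were seen, here and in the comparisons that follow.

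Among genes outside the ERK lists, the neuropeptide precursor gene Vgf rose 81.2-fold (6.34 ± 0.37), Aldh1a3, which encodes a retinoic acid synthesising enzyme, 77.0-fold (6.27 ± 0.35), and Cyp26a1, which encodes a retinoic acid degrading enzyme, by 5.84 ± 0.34. Lefty1, which encodes a Nodal antagonist, changed by -6.10 ± 0.54 and Dkk3 by -4.02 ± 0.50. Of 17 measured Wnt targets 9 rose and 2 fell (Notum, -0.86, and Ccnd1), with a median of 1.00 (adjusted p = 0.022; adjusted p = 0.16 with an estimated correlation). Counts of 9 that rose and 3 that fell were obtained adjusted over the list alone. Sp5 rose by 2.82 ± 0.33 and Brachyury (T) by 2.38 ± 0.28. Of 12 neural progenitor genes 7 fell and 3 rose (Sox11, 0.89, Pax6 and Nes), with a median of -0.83 (adjusted p = 0.042; adjusted p = 0.49 with an estimated correlation). Counts of 8 that fell and 3 that rose were obtained adjusted over the list alone. Of 22 cholesterol synthesis genes 7 rose and Mvk (-0.69) fell, with a median of 0.27 (adjusted p = 0.042; adjusted p = 0.63 with an estimated correlation). Counts of 8 that rose and 1 that fell were obtained adjusted over the list alone. Of 15 BMP and SMAD targets 8 fell and 3 rose (Id1, 3.26 ± 0.53, Msx1, 4.78 ± 0.31, and Skil, 1.23), with a median of -0.40 (adjusted p = 0.042; adjusted p = 0.29 with an estimated correlation), the same counts as adjusted over the list alone. The Wnt call was lost without 4OHT replicate 3 (adjusted p = 0.11), and the neural call without 4OHT replicate 1 (0.054) or replicate 3 (0.098). The cholesterol call was lost without untreated replicate 1 (0.10) or 2 (0.079), 4OHT replicate 2 (0.069) or 3 (0.064) or MG132 replicate 3 (0.057). The BMP call was lost without untreated replicate 2 (0.056), 4OHT replicate 1 (0.053) or 4OHT replicate 2 (0.083), and with a replicate block (0.051). Of 16 settings other than leaving out 1 array, 8 ended the neural call, 5 the cholesterol, 4 the BMP and 3 the Wnt call. With normexp background correction the neural median turned to 0.04 (adjusted p = 0.62). Over the settings the adjusted p was at most 0.62 for neural genes, 0.49 for cholesterol genes, 0.12 for BMP targets and 0.24 for Wnt targets. The median ranged from -1.0 to 0.04, from 0.11 to 0.45, from -0.56 to -0.40 and from 0.23 to 1.13 in the same order. The cholesterol median was 0.41 without untreated replicate 3.

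Several lists did not pass the test with 4OHT. Of 20 primitive endoderm markers 2 were higher and none lower, with a median of -0.24 (adjusted p = 0.85), and the endoderm factors Gata6 (0.52 ± 0.49, adjusted p = 0.48) and Sox17 (0.45 ± 0.51, adjusted p = 0.57) were not called. This list also differed between the replicate 3 arrays and their partners (median 0.72, adjusted p = 1.9e-09; adjusted p = 0.13 with an estimated correlation). Of 15 mesendoderm genes 6 rose, Eomes (3.23 ± 0.20) and Evx1 (3.80 ± 0.24) among them, and 6 fell, with a median of 0.11, a mean of -0.20 and a downward test (adjusted p = 0.99). Of 14 trophoblast genes 7 rose, with Hand1 at 4.33 ± 0.54, and Ascl2 (-0.98) and Ets2 (-0.61) fell (adjusted p = 0.085). Fibroblast markers, looked at for feeder cells, rose in 4 of 13 (Thy1, Vim, Twist1 and S100a4) and fell in Fn1 (-0.42) and Pdgfrb (-1.57) (adjusted p = 0.12), with the surface protein gene Thy1 at 3.71 ± 0.19. Of 23 p53 targets 6 rose and 10 fell (adjusted p = 0.20). Of 14 general pluripotency genes 5 rose, among them Utf1 (0.86), Zfp281 (0.65), Dppa4 (1.20 ± 0.10) and Dppa2 (adjusted p = 0.071). Adjusted over the list alone, the counts that rose and fell in these lists were 1 and 0, 6 and 6, 7 and 2, 4 and 2, 6 and 10, and 6 and 0, in the order given. In all, 3731 genes rose and 3936 fell, a total of 7667 of 26836 genes tested, of which 2979 changed at least 2-fold. The split depended on the scaling: normexp background correction gave 7067 higher and 3257 lower, quantile normalization 2970 and 4846, and median centring 2390 and 5353. All arrays of this comparison lay on slide 1, so a slide term left the changes as they were. It altered only the estimate of the spread. The counts of 7657 with slide as a block and 6346 within slide 1 therefore do not test an effect of slide. With only the arrays compared 5072 genes were called.

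The second comparison, of MG132 for 30 min and then 6 h with untreated cells at 0 h, asked what proteasome inhibition changed without 4OHT. Hspa1a, which encodes an inducible heat shock protein, rose 26.3-fold (4.72 ± 0.16, adjusted p = 9.1e-08). Atf3, a stress-induced transcription factor, rose by 4.55 ± 0.30, and Ddit3, which encodes the stress factor CHOP, by 3.28 ± 0.14. Egr1 fell by 2.96 on the log2 scale (SE 0.21, adjusted p = 5.2e-06), and Spry4 and Myc changed by -2.46 ± 0.21 and -1.32 ± 0.18. Nanog fell by 1.57 (SE 0.13, adjusted p = 1.4e-05), and Tdgf1, which encodes a Nodal co-receptor, by 2.69 (SE 0.08, adjusted p = 9.1e-08). All 3 MG132 arrays lay on one side of all 3 untreated arrays in each of these genes.

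Of 23 p53 targets, 20 rose with MG132 and none fell, with a median of 1.80 (camera, adjusted p = 9.4e-10; adjusted p = 0.013 with an estimated correlation), the same counts as adjusted over the list alone. Plk2 rose by 3.74 ± 0.22, Perp by 3.01 ± 0.22 and the antiproliferative gene Btg2 by 2.80 ± 0.40, and the death receptor gene Fas was at least 18.8-fold higher. All 14 general pluripotency genes fell, with a median of -0.84 (adjusted p = 3.7e-08; adjusted p = 0.012 with an estimated correlation), also adjusted over the list alone. Sall1 changed by -1.43 ± 0.14 and the RNA-binding protein gene Lin28a by -1.38 ± 0.17. These 2 lists, here and in MG132 with 4OHT against 4OHT alone, were the 4 of 40 list calls in all comparisons that held with an estimated correlation. The camera p also rose where the estimate lay below the preset 0.01. For general pluripotency here (estimate -0.0022) it went from 2.4e-09 to 0.00022 before adjustment. For Wnt targets with 4OHT (-0.0077) it went from 0.0063 to 0.019. A call lost with the estimate therefore need not reflect correlation between members. Of 22 targets of the integrated stress response factor ATF4, 18 rose and none fell (median 1.58, adjusted p = 1.3e-06; adjusted p = 0.45 with an estimated correlation), the same counts as adjusted over the list alone, with Ddit4 at 3.52 ± 0.28. Of 16 LIF and STAT3 targets 11 fell, among them the cytokine signalling inhibitor Socs3 (-2.18 ± 0.14), and the receptor gene Osmr was at least 2.38-fold higher (median -1.18, adjusted p = 3.0e-05; adjusted p = 0.18 with an estimated correlation). Of 20 naive pluripotency genes 14 fell and Nr0b1 (0.55) rose (median -0.82, adjusted p = 3.9e-05; adjusted p = 0.16 with an estimated correlation), with Gbx2 at -1.77 ± 0.13, Klf2 at -1.66 ± 0.33 and Klf4 at -1.27 ± 0.28. Of 18 mitotic genes 11 fell and Cenpe (0.36) rose (median -0.43, adjusted p = 0.0016; adjusted p = 0.45 with an estimated correlation), with the ubiquitin-conjugating enzyme gene Ube2c at -1.19 ± 0.11 and the kinase gene Plk1 at -1.05 ± 0.12. Adjusted over the list alone the LIF, naive and mitotic counts were the same. The mitotic call was lost with quantile normalization (median -0.28, adjusted p = 0.063), and median centring gave a median of -0.76. The ATF4 median was 0.92 with normexp and also with probes above background on all 12 arrays.

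Of 17 formative and primed epiblast genes 9 fell, with Zic5 at -2.64 ± 0.37 and Otx2 at -1.38 ± 0.16, and Fgf5 (1.27) and Cdh2 (0.46) rose (median -0.64, adjusted p = 0.032; adjusted p = 0.39 with an estimated correlation). Counts of 10 that fell and 2 that rose were obtained adjusted over the list alone. Of 15 BMP and SMAD targets 7 fell, with Smad6 at -2.08 ± 0.34, and Msx2 (0.69) and Ski (0.83) rose (median -0.78, adjusted p = 0.039; adjusted p = 0.29 with an estimated correlation), as adjusted over the list alone. Without MG132 replicate 3, the only MG132 array on slide 2, these calls were lost (adjusted p = 0.087 and 0.077), as they were with slide as a block (0.076 and 0.068) and within slide 1 (0.094 and 0.073). These settings are not separate checks, since in each the change rests on MG132 replicates 1 and 2 against untreated cells. The median was the same in each, -0.56 for formative genes and -0.38 for BMP targets. Of 16 settings other than leaving out 1 array, 7 ended the formative call (medians -0.93 to -0.34, adjusted p up to 0.14) and 8 the BMP call (-1.12 to -0.35, up to 0.11). Slide as a block and arrays within slide 1 are both counted there. Slide and replicate blocks together kept the formative call (median -0.61, adjusted p = 0.030) and not the BMP call (-0.35, adjusted p = 0.071). Of 26 cytosolic heat shock genes 12 rose and 3 fell (Cacybp, -0.41, Hspa4, -0.40, and Fkbp4, -0.53; adjusted p = 0.071), with the small heat shock gene Cryab at 1.99 ± 0.22. Of 42 proteasome genes 6 rose and 7 fell, with a median of -0.05 (adjusted p = 0.50), with Psmd14 at 0.75 ± 0.10 and the assembly factor gene Psmg2 at -0.61 ± 0.10. Of 20 targets of the antioxidant factor NRF2 and of metals 7 rose and 4 fell (adjusted p = 0.56), with Osgin1 at 2.87 ± 0.22. Of 22 ERK immediate-early genes 5 rose (Fosl1, 4.33 ± 0.34, Jun, 2.08, Ier5, 1.79, Ccn2, 0.53, and Btg2) and 6 fell, with a median of 0.18 and a downward test (adjusted p = 0.99). Of 23 ERK feedback genes 3 rose (Dusp2, 2.28 ± 0.24, Phlda1, 1.71 ± 0.26, and Errfi1, 1.07) and 9 fell (adjusted p = 0.11). Of 19 endoplasmic reticulum chaperone genes 5 rose and 2 fell (adjusted p = 0.49). No member of the 2-cell-like list was called by limma (median 0.77, adjusted p = 0.85), and 0 of 11 passed at an unadjusted p of 0.05. Adjusted over the list alone, the counts that rose and fell in the heat shock, proteasome, NRF2, immediate-early, feedback and chaperone lists were 12 and 4, 4 and 6, 8 and 4, 6 and 6, 3 and 9, and 5 and 2. Outside the lists, the osteocalcin genes Bglap3 (5.89 ± 0.15) and Bglap2 (5.80 ± 0.21) rose; these are near-identical copies, as are Hspa1a and Hspa1b (3.85 ± 0.18), so which copy gave the signal is uncertain. In addition, the chemokine gene Cxcl10 rose by 5.06 ± 0.35. In all, 6471 genes rose and 5092 fell, a total of 11563, of which 4282 changed at least 2-fold; median centring gave 3605 higher and 9452 lower. With slide as a block 10435 genes were called, and 8942 within slide 1, where in both the change rests on MG132 replicates 1 and 2.

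**Figure D2:**
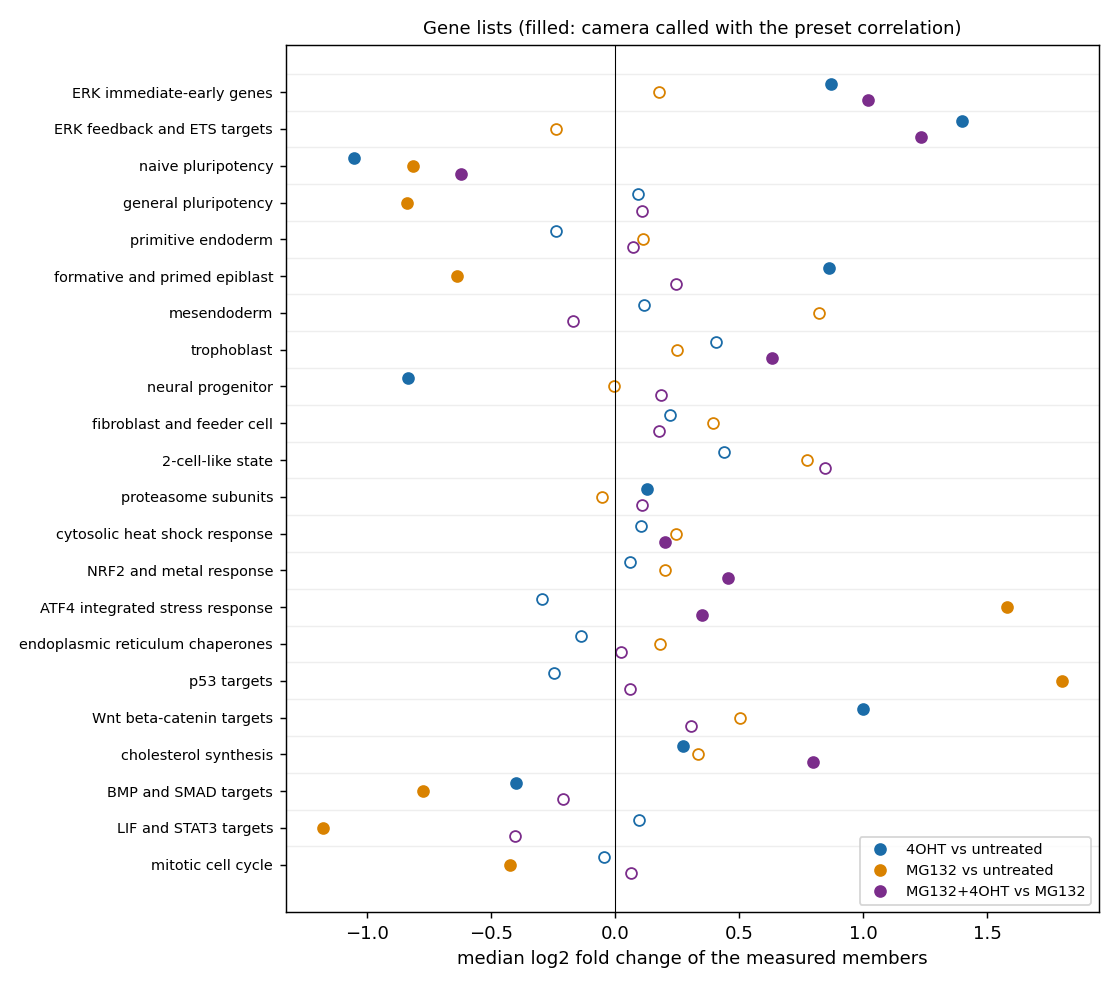
Median log2 fold change of the measured members of each of 22 gene lists in 3 comparisons, filled where camera called the list with the preset correlation. ERK feedback genes had medians of 1.40 and 1.23 for 4OHT without and with MG132, and p53 targets a median of 1.80 with MG132.

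The third comparison asked what 4OHT changed while the proteasome was inhibited. Egr1 rose 325-fold (8.35 ± 0.21, adjusted p = 6.2e-08), from the lowest level among the groups with MG132 alone. Spry4 rose 41.1-fold (5.36 ± 0.21, adjusted p = 2.6e-06) and Dusp6 by 2.20 ± 0.18 (adjusted p = 4.6e-05). Nanog fell by 1.45 (SE 0.13, adjusted p = 8.8e-05), and Ccl20 was at least 364-fold higher. In each of these genes all 3 arrays with both compounds lay on one side of all 3 MG132 arrays.

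Of 22 ERK immediate-early genes 15 rose and Srf (-0.64) fell (median 1.02, camera adjusted p = 1.2e-07; adjusted p = 0.16 with an estimated correlation), the same counts as adjusted over the list alone, with Egr3 at least 23.1-fold higher and Egr2 at 3.83 ± 0.32. Of 23 ERK feedback genes 15 rose and none fell (median 1.23, adjusted p = 5.0e-10; adjusted p = 0.12 with an estimated correlation). Counts of 17 and 1 were obtained adjusted over the list alone, and members included Phlda1 at 4.17 ± 0.26 and the urokinase receptor gene Plaur at 4.12 ± 0.24. Of 20 naive pluripotency genes 9 fell and 3 rose (Klf5, 0.64, Nr0b1, 0.78, and Mras, 0.74; median -0.62, adjusted p = 0.0017; adjusted p = 0.29 with an estimated correlation). Counts of 11 and 3 were obtained adjusted over the list alone. Of 22 cholesterol synthesis genes 14 rose and none fell (median 0.80, adjusted p = 4.9e-06; adjusted p = 0.30 with an estimated correlation). A count of 15 was obtained adjusted over the list alone, and members included the sterol demethylase gene Cyp51 at 1.32 ± 0.19. Of 20 NRF2 and metal response genes 11 rose and none fell (median 0.45, adjusted p = 0.0014; adjusted p = 0.49 with an estimated correlation). A count of 12 was obtained adjusted over the list alone, and members included the autophagy receptor gene Sqstm1 at 1.49 ± 0.15. With slide as a block the adjusted p was 1.6e-10 for immediate-early genes, 4.3e-13 for feedback genes, 0.021 for naive genes, 9.8e-06 for cholesterol genes and 2.5e-06 for NRF2 genes, and within slide 2 it was 4.2e-08, 3.8e-09, 0.021, 4.2e-06 and 0.00016. In both settings the naive median was -0.35 and the NRF2 median 0.83, with MG132 replicate 3 as the only control on slide 2. NRF2 genes were lower in the replicate 3 arrays (median -0.26, adjusted p = 8.5e-07; adjusted p = 0.14 with an estimated correlation). Slide and replicate blocks together gave medians of -0.54 for naive and 0.52 for NRF2 genes (adjusted p = 0.0033 and 1.5e-05).

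Of 22 ATF4 targets 4 rose (Ddit3, 1.47 ± 0.14, Ppp1r15a, Cebpb and Mthfd2, 0.43) and none fell (median 0.35, adjusted p = 0.017; adjusted p = 0.74 with an estimated correlation), the same counts as adjusted over the list alone. Of 14 trophoblast genes 6 rose, with Tead4 at 2.44 ± 0.20, and Ascl2 (-1.62) fell (median 0.63, adjusted p = 0.038; adjusted p = 0.46 with an estimated correlation). Counts of 8 and 1 were obtained adjusted over the list alone. Of 26 heat shock genes 10 rose, with the co-chaperone gene Dnajb1 at 0.98 ± 0.08, and Hspb8, Fkbp4 (-0.34) and Dnajb4 (-0.75) fell (median 0.20, adjusted p = 0.0496; adjusted p = 0.59 with an estimated correlation). Counts of 12 and 3 were obtained adjusted over the list alone. The ATF4 call was lost without MG132 replicate 3 (median 0.19, adjusted p = 0.19) or MG132+4OHT replicate 1 (0.051) and with quantile normalization (0.051). The ATF4 median was 0.61 with slide as a block and within slide 2 (adjusted p = 9.8e-06 and 0.00013), where MG132 replicate 3 was the only control on the slide. ATF4 targets were lower in the replicate 3 arrays (median -0.29, adjusted p = 1.5e-07; adjusted p = 0.18 with an estimated correlation), and slide and replicate blocks together gave 0.47 (adjusted p = 0.00026). The trophoblast call was lost without 4OHT replicate 1 (0.063) or MG132 replicate 3 (0.061), with a replicate block (0.074) and within slide 2 (0.064). The heat shock call was lost with slide as a block (0.11), within slide 2 (0.14), with a replicate block (0.071) and without any of untreated replicates 1 to 3 (0.060, 0.066, 0.055), 4OHT replicate 2 (0.065), MG132 replicates 1 and 2 (0.060, 0.069) or MG132+4OHT replicates 1 and 2 (0.077, 0.057). Of 16 settings other than leaving out 1 array, 11 ended the heat shock call (medians 0.05 to 0.25, adjusted p up to 0.50) and 6 the trophoblast call (0.32 to 0.79, up to 0.16). Klf4 (-1.24) passed the test but not with slide as a block (adjusted p = 0.11). The call of Cebpb (1.05, adjusted p = 0.031) was lost within slide 2 (0.14), with only the arrays compared (0.061), median centring (0.062), no filter (0.065) or slide and replicate blocks together (0.12). It was also lost without MG132 replicate 2 (0.057) or 3 (0.092) or MG132+4OHT replicate 1 (0.11) or 2 (0.11), and that of Ppp1r15a within slide 2 (0.051). Formative genes had a median of 0.25 (adjusted p = 0.22), with Etv4 at 2.29 ± 0.14. They passed the test with slide as a block (median 0.41, adjusted p = 0.013), and within slide 2 the adjusted p was 0.0502. Endoplasmic reticulum chaperones (median 0.02, adjusted p = 0.55) also passed with slide as a block (0.20, adjusted p = 0.020), and the 2-cell-like list (0.85, adjusted p = 0.63) within slide 2 (2.12, adjusted p = 0.042). The 2-cell-like median of the replicate 3 arrays, to which the control of slide 2 belongs, was -2.0 (adjusted p = 9.0e-09; adjusted p = 0.056 with an estimated correlation). Slide and replicate blocks together gave 0.22 for formative genes (adjusted p = 0.0080), 0.19 for the chaperones (adjusted p = 0.019) and 0.64 for the 2-cell-like list, which did not pass (adjusted p = 0.057). Primitive endoderm markers (0.42, adjusted p = 0.044, against 0.07 and 0.78 without blocks) and fibroblast markers (0.15, adjusted p = 0.024, against 0.18 and 0.096) passed in that fit too. Gata6 and Sox17 were not called (0.69 and 0.48). With a replicate block Gata6 was called (adjusted p = 0.030) and the 2-cell-like list passed (adjusted p = 0.046).

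With 4OHT under MG132 3724 genes rose and 3385 fell, a total of 7109, of which 1944 changed at least 2-fold; median centring gave 2591 higher and 3579 lower. Only MG132 replicate 3 shared slide 2 with the arrays given both compounds: 2987 genes were called with slide as a block and 2090 within slide 2, where that single array was assumed to vary like the other groups, and the count was 4722 without MG132 replicate 2, 4674 without MG132+4OHT replicate 1 and 4620 without MG132+4OHT replicate 2. Of the genes called with 4OHT in the absence of MG132, 1901 rose and 1949 fell in both settings, where independent lists would share 518 and 496, and 167 were called in opposite directions. The 3850 genes called in the same direction in both became 2072 with slide as a block and 1335 within slides. The responses correlated at 0.63 across genes, which are not independent replicates. The fold changes of the pair of comparisons shared no arrays, but their calls used the same spread per gene, pooled over all arrays. Without 4OHT replicate 1, which enters only the response without MG132, 8825 genes were called under MG132 in place of 7109. The values of 518 and 496 do not allow for this shared spread. With only the arrays compared, 2962 genes were called in the same direction in both, in place of 3850.

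MG132 was also compared in the presence of 4OHT. Hspa1a rose 79.5-fold (6.31 ± 0.16, adjusted p = 1.6e-08), and Gdf15, which encodes a stress-induced cytokine, rose 72.3-fold (6.18 ± 0.36). Gbx2, which rose with 4OHT alone, changed by -4.97 ± 0.13, and Cyp26a1 by -4.41 ± 0.34. Of 23 p53 targets 20 rose and none fell (median 2.15, camera adjusted p = 2.5e-09; adjusted p = 0.013 with an estimated correlation). A count of 21 was obtained adjusted over the list alone. All 14 general pluripotency genes fell (median -1.21, adjusted p = 7.7e-09; adjusted p = 0.012 with an estimated correlation), also adjusted over the list alone. Of 22 ATF4 targets 20 rose and none fell (median 2.07, adjusted p = 2.3e-08; adjusted p = 0.38 with an estimated correlation). A count of 21 was obtained adjusted over the list alone. Of 16 LIF and STAT3 targets 11 fell and Osmr, not well above background with 4OHT alone, was called higher (median -0.62, adjusted p = 3.7e-05; adjusted p = 0.18 with an estimated correlation), as adjusted over the list alone. Of 17 formative genes 11 fell and none rose (median -1.04, adjusted p = 0.00030; adjusted p = 0.16 with an estimated correlation). Counts of 11 and 1 were obtained adjusted over the list alone. Of 22 cholesterol genes 13 rose and none fell (median 0.78, adjusted p = 0.0022; adjusted p = 0.49 with an estimated correlation). A count of 14 was obtained adjusted over the list alone. Of 18 mitotic genes 11 fell and 3 rose (Aurka, 0.44, Cenpe, 0.62, and Cenpf, 0.51; median -0.39, adjusted p = 0.0078; adjusted p = 0.49 with an estimated correlation), as adjusted over the list alone. Of 20 naive genes 9 fell and Nr0b1 (0.56) and Jam2 (0.56) rose (median -0.39, adjusted p = 0.011; adjusted p = 0.39 with an estimated correlation). Counts of 10 and 2 were obtained adjusted over the list alone. With slide as a block the mitotic (adjusted p = 0.14) and naive (0.069) calls were lost, and 5337 genes were called in place of 13481 (7879 higher and 5602 lower), of which 5402 changed at least 2-fold; median centring gave 5057 higher and 8003 lower. The formative median with slide as a block was -0.35 (adjusted p = 0.031). Several lists passed with slide as a block that did not pass without it. These were neural genes (median 1.08, adjusted p = 0.021, against 0.70 and 0.17) and NRF2 genes (0.51, adjusted p = 0.0013, against 0.38 and 0.089). Endoplasmic reticulum chaperones (0.59, adjusted p = 0.0035, against 0.45 and 0.13) and heat shock genes (0.17, adjusted p = 0.0499, against 0.38 and 0.069) did so too. The slide term rested on MG132 replicate 3 against MG132 replicates 1 and 2, and in the replicate 3 arrays neural genes had a median of -0.46 (adjusted p = 0.0014; adjusted p = 0.12 with an estimated correlation) and NRF2 genes of -0.26. With slide and replicate blocks together NRF2 genes (0.35, adjusted p = 0.018) and chaperones (0.64, adjusted p = 0.0043) passed, as did primitive endoderm markers (0.41, adjusted p = 0.044, against 0.18 and 0.76 without blocks), and neural (0.76, adjusted p = 0.077) and heat shock genes (0.19, adjusted p = 0.075) did not. That fit gave -0.78 for formative genes (adjusted p = 0.00080), kept the mitotic call (adjusted p = 0.048) and ended the naive one (0.052). Of 15 settings other than leaving out 1 array, 4 ended the naive and 2 the mitotic call. Normexp gave medians of 1.29 for ATF4 targets and -0.62 for formative genes, and median centring -0.63 for mitotic and for naive genes. No slide held both groups, so no within-slide value could be had for this comparison.

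The last comparison tested whether the 4OHT response itself differed with MG132. Of the 4OHT responses, only the one without MG132 was measured from cells at 0 h. The rise of Egr1 was larger with MG132 by 5.25 ± 0.30 on the log2 scale (adjusted p = 3.8e-05) and that of Spry4 by 2.03 ± 0.30 (adjusted p = 0.0039), whereas the difference for Dusp6 was -0.13 ± 0.26 (adjusted p = 0.82). Egr1 and Spry4 had both fallen with MG132 alone, so these rises started lower, and the fall of Spry4 exceeded its difference. Lefty1, which fell with 4OHT alone, differed by 5.88 ± 0.76 (adjusted p = 0.0024). The response of Gbx2 differed by -3.21 ± 0.18 (adjusted p = 3.8e-05), and that of Vgf by -3.75 ± 0.53. The difference was 2.07 ± 0.19 for Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, and 1.86 ± 0.20 for Ddit3. The call of Spry4 was lost with normexp background correction (0.41, adjusted p = 0.29), and that of Cdkn1a with the mean over probes (1.55, adjusted p = 0.078).

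**Figure D3:**
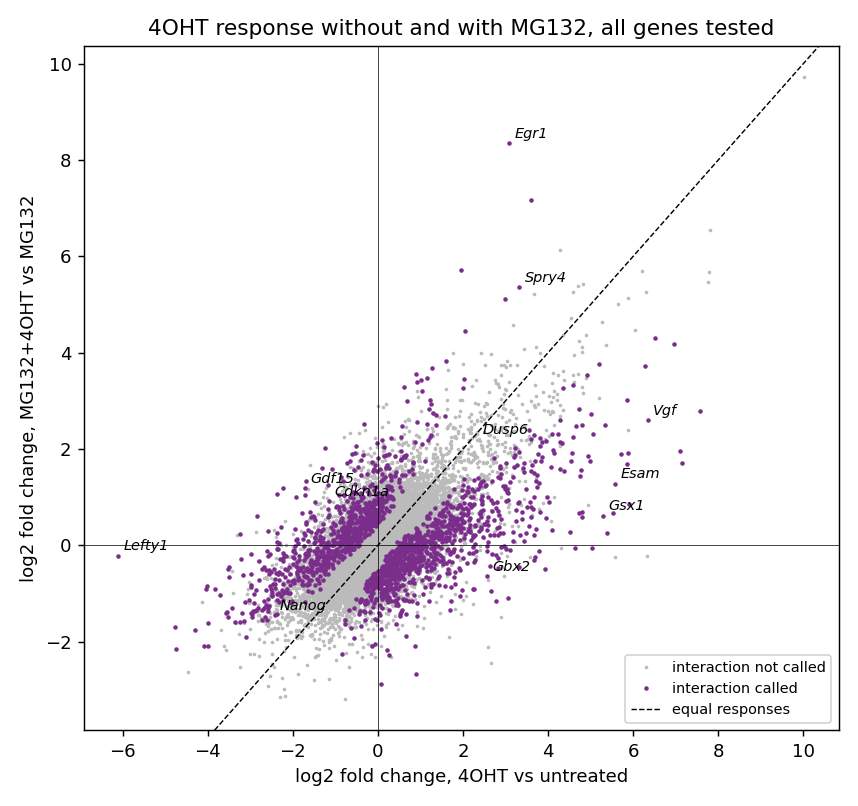
Log2 fold change with 4OHT in the absence (horizontal) and presence (vertical) of MG132 for the genes tested, each point 1 gene, purple where the difference was called (1759 genes) and the dashed line marking equal responses. Egr1 and Spry4 lay above the line and Vgf, Esam, Gsx1 and Gbx2 below it.

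Of 22 ATF4 targets 4 had a positive difference (Ddit3, Cebpb, Ppp1r15a and Cth, 0.94) and none a negative one (median 0.47, camera adjusted p = 0.00024; adjusted p = 0.51 with an estimated correlation). A count of 6 was obtained adjusted over the list alone. No cholesterol gene was called by limma, over all genes or adjusted over the list alone, and 5 of 22 passed at an unadjusted p of 0.05, with a list median of 0.44 (adjusted p = 0.0016; adjusted p = 0.49 with an estimated correlation). Of 20 NRF2 and metal response genes Hmox1 and Gclm were called (median 0.50, adjusted p = 0.0029; adjusted p = 0.50 with an estimated correlation). A count of 3 was obtained adjusted over the list alone. With slide as a block the adjusted p was 1.4e-08, 0.0070 and 4.7e-06 for these lists, and within slides 3.5e-08, 0.0090 and 7.8e-06. In both settings the ATF4 median was 0.79 and the NRF2 median 0.80, again with MG132 replicate 3 as the only control on slide 2, whose replicate number had lower ATF4 (median -0.29) and NRF2 genes (-0.26). Slide and replicate blocks together gave 0.70, 0.50 and 0.57 for ATF4, cholesterol and NRF2 genes (adjusted p = 1.1e-05, 5.4e-06 and 1.7e-05). The cholesterol median was 0.29 without untreated replicate 3. Of 17 formative genes 7 had a negative difference (median -0.34, adjusted p = 0.0062; adjusted p = 0.29 with an estimated correlation), with 8 negative and 2 positive adjusted over the list alone. Of 14 general pluripotency genes Sox2 and Foxd3 did (median -0.19, adjusted p = 0.017; adjusted p = 0.16 with an estimated correlation). A count of 4 was obtained adjusted over the list alone. These calls were lost with slide as a block (adjusted p = 0.14 and 0.096) and within slides (0.16 and 0.099). The formative call was kept with slide and replicate blocks together (median -0.73, adjusted p = 0.033), and the general pluripotency call was not (adjusted p = 0.10). The formative median was -0.77 with slide as a block and -0.62 without 4OHT replicate 2, and the general pluripotency median was -0.11 without untreated replicate 1. Of 12 neural genes 4 had a positive difference (Dll1, Pax3, Tubb3 and Zic1, which like Pax3 was not well above background with 4OHT alone; median 0.89, adjusted p = 0.019; adjusted p = 0.45 with an estimated correlation). A count of 7 was obtained adjusted over the list alone. Of 17 Wnt targets 5 a negative one (Sp5, Brachyury (T), Myc, Tcf7, -0.81, and Tnfrsf19, -0.54; median -0.54, adjusted p = 0.021; adjusted p = 0.16 with an estimated correlation). A count of 7 was obtained adjusted over the list alone. The neural call was lost without 4OHT replicate 3 (0.081) or MG132 replicate 3 (0.094), and the Wnt call without 4OHT replicate 3 (0.11), and the Wnt median was -0.84 without 4OHT replicate 1. The neural median was 0.04 with normexp (adjusted p = 0.71) and 0.10 with probes above background on all 12 arrays (adjusted p = 0.52), against 0.91 with slide as a block (adjusted p = 0.00021) and 0.79 with slide and replicate blocks together (adjusted p = 0.0049). Of 15 settings other than leaving out 1 array, 5 ended the general pluripotency call (adjusted p up to 0.27), 4 the neural (0.71), 3 the formative (0.16) and 1 the Wnt call (0.24). The medians ranged from -0.28 to -0.07, from 0.04 to 0.99, from -0.77 to -0.24 and from -0.92 to -0.25 in that order. Naive genes (median 0.41, adjusted p = 0.13), endoplasmic reticulum chaperones (0.18, adjusted p = 0.12) and BMP targets (0.72, adjusted p = 0.085) did not pass. They did with slide as a block (0.34, 0.37 and 0.49, adjusted p = 0.032, 0.0013 and 0.016) and within slides (adjusted p = 0.041, 0.0015 and 0.021), and with slide and replicate blocks together (0.33, 0.37 and 0.89, adjusted p = 0.037, 0.0021 and 0.019). In that last fit primitive endoderm markers (0.35, adjusted p = 0.019, against 0.20 and 0.64 without blocks) and p53 targets (0.38, adjusted p = 0.019, against 0.27 and 0.13) passed as well. Immediate-early genes differed in both directions, 5 positive (Egr1, Fosb, 2.30 ± 0.39, Egr2, 2.22, Fos, 1.43, and Ccn2, 1.09) and 4 negative (Ier5, -2.69 ± 0.19, Fosl1, -2.30, Myc and Nr4a1, -0.79; adjusted p = 0.66), and feedback genes had a median of -0.15, a mean of 0.06 and a downward test (adjusted p = 0.83). Of the members named here, Sox2, Pax3, Myc, Cebpb, Hmox1 and Gclm lost their calls when single arrays were left out, with adjusted p of at most 0.12 for Hmox1, without MG132+4OHT replicate 2. The calls of Fosb (0.052), Sox2 (0.16), Pax3 (0.17), Myc (0.15), Hmox1 (0.061) and Gclm (0.082) were lost with slide as a block, and within slides also those of Dll1 (0.085), Cebpb (0.086), Sp5 (0.055), Brachyury (T) (0.088) and Foxd3 (0.077). With normexp the differences of Pax3 and Brachyury (T) were 0.04 and -0.57 (adjusted p = 0.91 and 0.065).

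The difference was called in 1759 genes, 790 positive and 969 negative, of which 1041 differed at least 2-fold. The split depended on the scaling, with 905 positive and 638 negative after median centring, 995 and 912 after quantile normalization, and 659 and 1191 with normexp. Among 1273 genes whose average rise with 4OHT was at least 2-fold, the median was 1.84 without and 1.35 with MG132, and 295 had a called smaller and 57 a called larger response. Among 1092 genes with an average fall of that size the medians were -1.59 and -1.09, with 177 smaller and 11 larger. The direction depended on how genes were chosen. Of the 1105 genes that rose at least 2-fold with 4OHT under MG132, 110 had a smaller and 135 a larger response with MG132 (medians 1.37 without and 1.55 with it), and of the 839 that fell 49 and 90 (-1.11 and -1.27). Of the 1483 chosen on their rise without MG132, 471 had a smaller and 24 a larger one (1.70 and 0.93), and of the 1496 that fell 325 and 0 (-1.43 and -0.78). The count was 802 with slide as a block and 462 within slides. It was 1108 and 1066 without untreated replicate 1 or 2, 1127 and 1090 without MG132 replicate 1 or 2, and 1087 and 1037 without MG132+4OHT replicate 1 or 2.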

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

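The tests of lower detection, of a deviation shared by the replicate 3 arrays and of slide or position were chosen only after the results were seen, as were the comparison of the replicate 3 arrays with their partners and the fit with slide and replicate blocks together. The results of this part are those where the 4OHT response differed between cells with and without MG132 in a test of the difference itself.

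The difference was called in 1759 genes. List medians of the difference were -0.19 for general pluripotency, -0.34 for formative and primed epiblast, 0.89 for neural progenitor, 0.50 for NRF2 and metal response, 0.47 for ATF4 targets, -0.54 for Wnt targets and 0.44 for cholesterol synthesis. Single genes with a positive difference were Lefty1 (5.88), Egr1 (5.25), Tunar (3.48), Fgf10 (3.41), Dkk3 (3.19), Tmem163 (3.12), Lrrc15 (3.03), Gdf15 (2.91), Dll1 (2.42), Fosb (2.30), Id3 (2.17), Cdkn1a (2.07), Spry4 (2.03), Ddit3 (1.86), Cebpb (1.86), Hspa1a (1.59), Ppp1r15a (1.40), Spp1 (1.28), Hspb8 (1.23), Tubb3 (1.11), Gata2 (1.1), Trp53inp1 (1.01), Dnajb1 (0.98), Nanog (0.98), Gclm (0.82), Ets2 (0.73) and Hmox1 (0.64). Those with a negative difference were Gsx1 (-4.67), Esam (-4.30), Edn2 (-4.21), Arntl2 (-3.94), Mfap3l (-3.75), Vgf (-3.75), Shisal1 (-3.60), Thy1 (-3.37), Msx1 (-3.22), Gbx2 (-3.21), Ier5 (-2.69), Sp5 (-2.61), Dusp2 (-2.49), Brachyury (T) (-2.07), Foxd3 (-1.81), Pou3f1 (-1.79), Fgf5 (-1.64), Dnmt3a (-1.49), Perp (-1.44), Bcl3 (-1.40), Nr5a2 (-1.36), Xbp1 (-1.30), S100a4 (-1.25), Eomes (-1.21), Myc (-1.15), Il17rd (-0.70), Psmg2 (-0.63) and Sox2 (-0.61). For Gsc (3.07), Pax3 (1.36) and Osmr (-2.36) the values are only fitted ones, neither measured differences nor bounds, because Gsc and Pax3 were not well above background with 4OHT alone, nor Osmr in cells without MG132. Tmem163 and Dll1 were so on 1 of the 3 4OHT arrays. Leaving out 1 array ended the calls of Fgf10, Dkk3, Tmem163, Il17rd, Nr5a2, Spp1, Sox2, Pou3f1, Fgf5, Eomes, Ets2, Pax3, S100a4, Psmg2, Gclm, Hmox1, Cebpb, Xbp1, Perp, Myc and Osmr, and this happened for at least 1 array of every group; the highest adjusted p was 0.12, for S100a4 without untreated replicate 1. Of the 58 genes, 23 lost their calls with slide as a block, with an adjusted p of at most 0.24. They were Tunar (0.082), Fosb (0.052), Gata2 (0.078), Nanog (0.059) and the genes just named other than S100a4 and Cebpb. Within slides 33 of 57 genes did, these 23 with Cebpb (0.086), Gsc (0.075), Lrrc15 (0.071), Gdf15 (0.078), Dll1 (0.085), Hspb8 (0.066), Trp53inp1 (0.056), Sp5 (0.055), Brachyury (T) (0.088) and Foxd3 (0.077). In both settings MG132 replicate 3 was the only MG132 array on slide 2, so they carry the replicate 3 deviation. Slide and replicate blocks together ended 24 of the 58 calls. A replicate block ended those of Fgf5 (0.070), S100a4 (0.064) and Xbp1 (0.060). Normexp moved 22 differences by over 1.5 times and ended 7 calls, among them those of Gsc (0.49, adjusted p = 0.16), Tmem163 (0.58, adjusted p = 0.35), Pax3 (0.04, adjusted p = 0.91) and Osmr (-0.37, adjusted p = 0.26). No filter ended 11 of the 58 calls, median centring 10, the mean over probes 7, quantile normalization 5, slide as a random block 4 and the restriction to replicates 1 and 2 ended 3. With the mean over probes the difference of Nanog was 0.20 (adjusted p = 0.76) and that of Il17rd -0.37 (adjusted p = 0.40).

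The first pattern is the smaller 4OHT response with MG132 among 2365 genes chosen on the average of both responses, whereas larger called responses outnumbered smaller ones among genes chosen on the response with MG132 (135 against 110 risen and 90 against 49 fallen). Called smaller responses exceeded larger ones by 404 (472 against 68). The highest of 20 simulations with no difference, the real spread of each group and the same choice of genes gave 1. Noise was drawn independently for each gene there, whereas the real arrays also deviated together across genes. The simulations therefore argue only against unequal spread of independent noise with that choice of genes. With only the MG132 array on slide 2 as control, the median difference in the direction of the response was -0.51 (95% interval from a bootstrap over genes -0.57 to -0.46), the value over all arrays. This value does not decide on a slide offset, because it rests on that single array. The interval leaves out the spread between arrays. The MG132 response of that array had a slope of 1.07 relative to the MG132 arrays on slide 1. The slope cannot test a narrower range on slide 2, because its genes and its reference came from a comparison of slide 2 with slide 1. A slide offset would raise the slope as well. Both values rest on 1 array, which is of replicate 3 and shares the deviation described below. Slide and the presence of both compounds therefore cannot be told apart. A smaller response to 4OHT while the proteasome is inhibited stays possible as a hypothesis, and so does a change over 6 h in culture, which enters only the response measured from cells at 0 h and for which no untreated array at 6 h allowed a test.

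The second pattern is a weaker response in 4OHT replicate 3, with slopes of 0.97, 0.98 and 0.74 for replicates 1 to 3 over 1944 genes called at least 2-fold in the comparison under MG132. Admixture of untreated RNA would need 1 mixing fraction, but the median was 0.376 over 1105 risen and 0.200 over 835 fallen genes (difference -0.18, interval from a bootstrap over genes -0.22 to -0.14). These values go against admixture as the whole cause. They rest on 1 array, and the interval leaves out the spread between arrays, so admixture is not excluded. Lower detection and a deviation shared by all replicate 3 arrays stay open, since each test rests on 1 array: replicate 2, with fewer probes above background, had a slope higher by 0.24, and MG132+4OHT replicate 3 had a relative slope of 0.95 against 0.76 (difference 0.18). In the replicate 3 arrays the median was -0.15 for ERK immediate-early genes (adjusted p = 0.049; adjusted p = 0.44 with an estimated correlation) and -0.17 for ERK feedback genes (adjusted p = 0.029; adjusted p = 0.37 with an estimated correlation). No biological explanation was tested.

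The third pattern is that the replicate 3 arrays deviated together, with 2721 genes called (1402 higher and 1319 lower). Only 1 of 81 choices of 1 array per group, the real one, called as many, and the highest other called 29. Every other choice leaves a replicate 3 array among the partners, which puts a shared deviation into the spread. The comparison was also chosen after the results were seen, so this share does not exclude chance. Slide or position is argued against by the untreated and 4OHT replicate 3 arrays, which lay on the same slide as their partners and correlated at 0.23 in their deviations across genes. A shared day or culture is not named in the labels and was not tested.

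For each pair of groups the 6 arrays make 10 splits, too few for a share under 0.05, and 1 split in each, the real one, called as many genes as observed. The real counts were 7667, 11563, 7109 and 13481 and the highest other splits called 1, 0, 0 and 1, in the order of the report. For the difference of responses 2 of 100 assignments, the real one included, called as many as 1759, and the highest other called 2094. This does not decide on chance, because assignments that exchange arrays without MG132 put the 4OHT response itself into the spread, and these called at most 700. The others, which exchanged arrays with MG132 alone, called 2094, 1654, 1509, 1428, 597, 576, 431 and 403 genes. There the exchange removes the 4OHT response with MG132, which by itself makes a difference. For the 3850 genes called alike in both settings 1 of 100 assignments, the real one, called as many, and the highest other called 1. This does not decide on chance either. Every other assignment exchanges treated and control arrays in at least 1 of the 4OHT comparisons, which by itself removes or reverses the response there.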

How the results depend on the processing

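The slide block combined with the replicate block and the restriction to replicates 1 and 2 were chosen only after the data were seen; the other alternatives were planned. Over all alternatives other than leaving out 1 array, named genes kept direction and side of the threshold in 5175 cases, weakened in 282 and strengthened in 22, and lists did so in 1559, 80 and 76. With 1 array left out the numbers were 3732, 245 and 7 for genes and 1269, 36 and 15 for lists. The series-wide values were the same numbers as the scanner values, so their 332 gene and 110 list cases could not change. They are included in the first totals and among the settings counted for each list call. One list turned: with normexp the proteasome subunits list tested downward for 4OHT against untreated, with a median of 0.059 (adjusted p = 0.90). With the main setting 7 of its 42 members rose (5 adjusted over the list alone) with a median of 0.13 (adjusted p = 0.047; adjusted p = 0.78 with an estimated correlation), and the call was lost without untreated replicates 1 and 2 (0.18, 0.091), 4OHT replicates 2 and 3 (0.11, 0.15), MG132 replicates 1 and 3 (0.050, 0.057) or MG132+4OHT replicates 1 and 2 (0.051, 0.054). Of 16 other settings 8 ended this call, with medians from -0.03 with median centring to 0.17 and adjusted p from 0.0060 to 0.90. Counts of changed genes are given for 4OHT against untreated, MG132 against untreated, 4OHT under MG132, MG132 under 4OHT, the difference of responses and the genes called alike, as far as they moved by over 1.5 times. A 2-fold minimum gave 2979, 4282, 1944, 5402, 1041 and 1109, fewer by construction. No filter gave 14466 for 4OHT, and only the arrays compared 5072. Array weights gave 14121 for 4OHT under MG132, 4687 for the difference and 5890 called alike. Slide as a fixed block gave 2987, 5337, 802 and 2072 from the third result on, the slide and replicate blocks together 2312, 4833, 804 and 1735, and arrays within a slide 2090 for 4OHT under MG132, 462 for the difference and 1335 called alike, where fewer arrays carry each comparison. Only replicates 1 and 2 gave 2910 for the difference. Apart from these constructions the cause was not tested. The replicate block gave 8829, 12663, 8635, 14487, 2565 and 4777, all within 1.5 times, and among list calls ended those of BMP targets with 4OHT, and of trophoblast and heat shock genes with 4OHT under MG132, and among named genes those of Fgf5, S100a4 and Xbp1 in the difference. It added calls of Gata6 (0.030), Cdk1 (0.046) and the 2-cell-like list (0.046) with 4OHT under MG132 and of Sc5d (0.0098) and Aurka (0.049) in the difference, and changed no other call of a named gene or list. Slide as a random block had a correlation of 0.096. Leaving out 1 array gave ranges of 5763 to 8578, 9530 to 13060, 4620 to 8825, 11465 to 14342, 1037 to 2529 and 2780 to 4504. Scaling moved the median of all genes, 0.03 for 4OHT and 0.07 for MG132 in the main setting, to 0.16 and 0.09 with normexp, -0.07 and -0.04 with quantile normalization and -0.13 and -0.27 with median centring. Signal over background limits the genes whose fold is given as a bound.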

Other observations

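The test of a loss of ERK signalling was chosen only after the difference of responses was seen, and so was the comparison of the replicate 3 arrays with their partners.

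In that comparison the arrays of replicate 3 held more RNA of Atp1a4 (2.51), Il34 (1.74) and Khdc3 (1.72) and less of the oestrogen receptor gene Esr1 (-2.56) and of Zscan4a (-2.45), a marker of the 2-cell-like state whose near-identical copies were not separated with certainty. These genes were chosen after their values were seen. The 2-cell-like list had a median of -2.0 (adjusted p = 9.0e-09; adjusted p = 0.056 with an estimated correlation), ATF4 targets -0.29 (adjusted p = 1.5e-07; adjusted p = 0.18 with an estimated correlation), NRF2 and metal response genes -0.26 (adjusted p = 8.5e-07; adjusted p = 0.14 with an estimated correlation) and cholesterol genes 0.24 (adjusted p = 0.0014; adjusted p = 0.18 with an estimated correlation). Each group holds 1 replicate 3 array, so the comparisons over all arrays are balanced for it. Values within slide 2 or with slide as a block are not, because replicate 3 is the only MG132 array on slide 2.

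A hypothesis is that the smaller 4OHT response with MG132 reflects a general loss of ERK signalling. Of the ERK list members 39 had a called average response. Their median difference in the direction of the response was -0.18 (95% interval from a bootstrap over genes -0.36 to 0.25), where the fall seen over all chosen genes would need -0.56. The interval lies above that value, but it leaves out the spread between arrays, and single members went strongly in both directions. The test therefore does not decide whether ERK targets lost their measured response in the same proportion as other genes. Slide and hours in culture were left open too. Egr1 and Spry4 rose more with MG132, from levels that MG132 alone had lowered. Ier5 and Dusp2 rose less, from levels that MG132 alone had raised. The fall of Spry4 with MG132 alone exceeded its difference of responses, and the call of that difference was lost with normexp background correction.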
